A study of Mus musculus with 19 samples.

How the data were processed

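The samples were primary cultures of mouse trophoblast cells, the epithelial cells of the placenta, prepared from placentas on day 10 of pregnancy. Per the labels the cells were enriched on 40% Percoll, left to adhere for 14 to 18 h and then kept in serum-free medium alone (control) or with recombinant mouse leptin at 50 ng/mL, and 1 well was taken per group. RNA was amplified, labelled with biotin and hybridized to Illumina mouse BeadChip arrays. There were 5 groups, namely control 1 h (n = 4), leptin 1 h (n = 4), leptin 6 h (n = 4), control 24 h (n = 3) and leptin 24 h (n = 4), in experiments numbered 15, 19, 27 and 28. The control 24 h sample of experiment 28 was not analysed here, and the design has no control at 6 h. In experiments 15, 27 and 28 the column headers of the control 1 h arrays carry a 0 where the labels say 1 h, and the labels were followed.

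The deposited file of each array gives, per the file headers, a mean signal per probe as linear intensity and a detection p-value, the probability that a signal so high comes from the array's negative controls. The submitters' processing notes name BeadStudio and limma, without versions. The deposited table for all arrays holds log2 values. It equals the log2 of the quantile-normalized signal of the probes shared by both array versions, without background subtraction, to within 5e-09. No chip number was given. The 4 arrays of experiment 19 other than control 24 h were of a smaller array version with 24048 targets, and the remaining 15 arrays were of a larger version with 24611. The 23189 probes that both versions carry were used. The depth of an array is its signal over background. Between 8128 and 10810 of the shared probes were detected at p under 0.01, and the mean signal ran from 639 to 1058. For arrays it is their number that limits the precision.

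From the intensity files, background was subtracted per array with limma's normal-exponential model driven by the detection p-values (offset 16), and the shared probes were quantile-normalized over the 19 arrays and put on the log2 scale. Probes detected at p under 0.01 on at least 3 arrays were kept (11222), and for each gene the probe of highest mean was taken, which left 10702 features, 3971 of them genes with a symbol and 6731 probes without one. A probe annotation table was not at hand. The target names of the form with 1 or 2 leading zeros carry NCBI gene numbers, which was checked on the data: 93.3% of 9196 such numbers are mouse gene numbers against 10.6% of 10257 numbers without a leading zero, and 1.22% of 328 olfactory receptor probes but 94.4% of 72 ribosomal protein probes were detected. In this way 8586 of the 23189 probes (37.0%) were named. The leptin receptor (Lepr), leptin (Lep) and Socs3, the STAT3-induced inhibitor of leptin signalling, had 0 named probes. A probe not detected on any array of a group has only a bound there, given as at least N-fold. It sets the mean of the brighter group against, per array, the higher of the probe's own signal and the lowest signal of a detected probe, on the normalized log2 scale. Probes of the Prl3d, Psg and Gzm families may hybridize to more than 1 member of their family.

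Groups were compared in R 4.3.3 with limma 3.58.1 (lmFit, contrasts.fit and eBayes, 11 residual and 4.14 prior degrees of freedom), with the 5 groups as terms and the experiment as a block. Features were called at a Benjamini-Hochberg adjusted p under 0.05, and the errors of log2 changes are standard errors (SE) of that fit. Per the labels and the series design the experiment number marks a shared preparation, so the numbers pair the samples. The pairing was checked in the data on deviations from the group mean. Their median r was 0.707 over the 36 pairs of arrays from the same experiment. Over pairs from different experiments and groups it was -0.270 (across features, which are not independent replicates). By this measure 18 of the 19 arrays were most like an array of their own experiment among the arrays of other groups. The exception was the control 24 h array of experiment 15, which was most like leptin 1 h of experiment 19 (r = 0.191). In plain correlation of log2 levels that array was closest to leptin 24 h of its own experiment (r = 0.992). Of the 36 pairs, 32 had r over 0.1, and the rest all held the control 24 h array of experiment 15. The lowest was -0.161, and without the control 24 h arrays the range was 0.535 to 0.958.

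Gene lists were tested with camera (preset correlation of 0.01, adjusted over the lists of a comparison), again with an estimated correlation, and with fry. Of 26 lists, the 22 with at least 5 tested members were tested. The genes named in the text follow a rule. For leptin against control at 1 h and at 24 h, control 24 h against control 1 h and leptin 6 h outside both controls, they are the 10 genes with the largest rise and the 10 with the largest fall among those called and changed in the same direction within every experiment. Where none was called, they are the 5 of smallest p in each direction that moved the same way in every experiment, given as values. For the other comparisons the numbers are 4 and 3. Up to 4 members of smallest p were taken from each list, and RIKEN, Gm, LOC and accession-like symbols were left out. The groups, comparisons, lists, this rule and most alternatives were fixed before the data were examined. Leptin 24 h against leptin 1 h was added afterwards, as were the alternatives with the array version as a block, with the larger version alone and without the control 24 h arrays of experiments 19 and 27.

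The fit was tested on simulated data with normal noise of the residual SD of each of the 10702 features, the same on all arrays. In these data 200 features were changed, and the other members of the cell cycle list were shifted by -0.5. The real groups differ in spread, so the shares need not hold for them, least of all with control 24 h. In control 24 h against control 1 h the fit recovered 16.4% of 1.5-fold, 59.7% of 2-fold and 95.5% of 4-fold changes, with 8.73% of calls false. At 1 h the shares for leptin were 22.4%, 73.1% and 98.5% (2.96% false), and at 24 h 22.4%, 58.2% and 93.9% (1.65% false). Other normalizations, filters, moderation, blocks, thresholds and left-out arrays were tried, and the closing section gives their effect. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.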

Results

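Gene expression was measured on 19 arrays, 1 per culture, in trophoblast cells with and without leptin, a hormone of fat tissue that signals through STAT3. The groups were control 1 h (n = 4), leptin 1 h (n = 4), leptin 6 h (n = 4), control 24 h (n = 3) and leptin 24 h (n = 4), from 4 experiments. In deviations from the group mean, 18 of the 19 arrays were most like an array of their own experiment among the arrays of other groups. The exception was the control 24 h array of experiment 15. In plain correlation of log2 levels, the control 24 h arrays of experiments 19 and 27 were closest to an array of experiment 15. There r was 0.9561 and 0.9558, against at most 0.9353 and 0.9539 with arrays of their own experiments. Detected probes numbered 10354 to 10810 on the 4 smaller-version arrays of experiment 19, and 9061 to 9660 on the larger-version arrays outside the control 24 h group. The lowest mean signals were those of the control 24 h arrays of experiment 27 (639, with 8128 probes detected) and of experiment 19 (642, with 9290). The first 3 principal components held 41.0%, 25.4% and 8.56% of the variance.

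**Figure D1:**
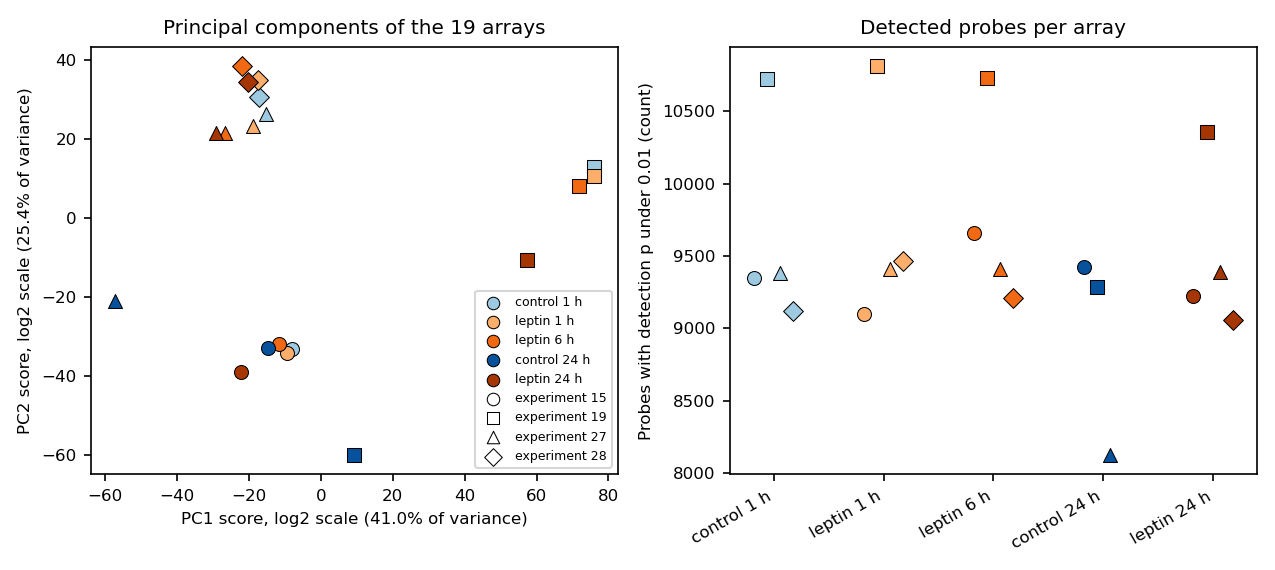
Each point is 1 array, with colour for the group and shape for the experiment. One panel plots the first against the second principal component (41.0% and 25.4% of the variance) and the other the detected probes (count) by group. The 4 smaller-version arrays of experiment 19 lie together, and the control 24 h arrays of experiments 19 and 27 lie apart from the other arrays of their own experiments.

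Does leptin change expression within 1 h? No gene passed the test at 1 h. In experiments 15, 27 and 28 the headers of the control arrays carry a 0, so the time match of those pairs rests on the labels. Among the genes that moved the same way in all 4 experiments, those of smallest p on the higher side included Slc4a3, an anion exchanger (log2 change 0.51 ± 0.24, SE, n = 4 pairs), and Tmem38a, a cation channel of intracellular membranes (0.41 ± 0.22). Others were Myh7, a myosin heavy chain (0.41 ± 0.20), Pacsin1, an endocytosis adaptor detected on 0 of 4 control arrays and given no fold, and Apol9b, an apolipoprotein L family gene (0.35 ± 0.15). On the lower side, Gpatch1 stood at -0.44 ± 0.24, Dcn, the matrix proteoglycan decorin, at -0.37 ± 0.21 and Vangl1, a planar cell polarity gene, at -0.37 ± 0.15. Arnt, the partner of the hypoxia-inducible factors, stood at -0.35 ± 0.20 and Ero1b, an oxidase of the endoplasmic reticulum, at -0.34 ± 0.19. The adjusted p of all 10 was 1. Slc4a3 rested on experiment 27, with 1.53 there and 0.09 to 0.21 in the others. At most 2 of 4 arrays in either group detected Slc4a3, Tmem38a, Myh7, Apol9b and Vangl1, and 3 of the controls and 2 with leptin detected Gpatch1 and Ero1b.

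None of the 22 lists was called at 1 h (lowest adjusted p = 0.556). The median of the direct leptin and STAT3 targets (10 of 27 tested, Socs3 not among them) was between -0.04 and 0.05 in the 4 experiments. That of the immediate early genes, which many stimuli induce within an hour (9 of 38 tested), was between -0.09 and 0.28. In limma 0 of 10702 features were called, with 21 at an unadjusted p under 0.05 against 535 expected by chance. The error of that fit pools groups that vary more. A limma fit of the 1 h arrays alone also called 0, with 443 at an unadjusted p under 0.05. It had a 95% confidence interval that reached a median factor of 1.16 to either side, against 1.34 with all arrays.

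After 24 h the cultures with leptin were compared with the control cultures of the same age, and no single gene passed. Among genes that moved the same way in the 3 experiments with both samples, those of smallest p on the higher side included Psmd11, a proteasome subunit (2.24 ± 0.48, SE), and Gng12, a G protein subunit (1.53 ± 0.24). They were followed by Tuba3a, an alpha-tubulin (1.15 ± 0.26), Marcksl1, an actin-binding protein (0.82 ± 0.17), and Lilrb4a, an inhibitory receptor of leukocytes (0.74 ± 0.17). Gphn, the scaffold protein gephyrin, stood at -0.88 ± 0.22, Rhobtb3 at -0.71 ± 0.17 and Sapcd2 at -0.53 ± 0.12. Orc3, a subunit of the origin recognition complex, and Tgfbr2, a TGF-beta receptor, were detected on 0 of 4 arrays with leptin, which leaves Orc3 at least 1.31-fold lower and Tgfbr2 without a fold. The adjusted p was 0.117 for Gng12 and 0.154 for the others. Psmd11 rested on experiments 19 and 27, with 3.46 and 2.68 there and 0.20 in experiment 15. Of the 2 further probes of Marcksl1, 1 went the other way. Of the 3 control arrays, 2 detected Gng12, Orc3 and Sapcd2, and 1 detected Psmd11, Tuba3a, Lilrb4a and Tgfbr2, while with leptin 3 of 4 detected Lilrb4a and 1 Sapcd2.

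Of the 22 lists, 1 was called at 24 h, the trophoblast giant cell genes, which include hormones of the prolactin family (10 tested, median log2 change 0.56, adjusted p = 2.3e-05). The call was lost with an estimated correlation (adjusted p = 0.399 with an estimated correlation). Without the control 24 h arrays of experiments 19 and 27 it was lost too, and another list was called instead. That fit leaves 1 control array at 24 h, so its list calls are not read further. Over all genes 0 members passed, and adjusted over the list alone 6 were higher. The placental lactogen genes Prl3d1, Prl3d2 and Prl3d3 had values of 1.16 ± 0.34, 1.5 ± 0.43 and 1.62 ± 0.43, and Prl7d1, a proliferin-related hormone gene, 2.14 ± 0.60 (adjusted p = 0.154 each). All of these had the opposite sign in experiment 15, where the list median was -0.09 against 0.81 in experiment 19 and 0.96 in experiment 27. The same pair of control arrays stood apart in their signal.

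In limma 0 of 10702 features were called at 24 h, with 1674 at an unadjusted p under 0.05, and a fit of the 24 h arrays alone called 0 with 637. The count rests on the control 24 h array of experiment 15. Without it 1812 features were called, without experiment 15 altogether 1263, and with array weights, in a fit that did not converge, 2531.

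Whether the effect of leptin differed between 24 h and 1 h was tested as a difference of differences, and no gene passed. By the rule, the higher side held Gng12 (1.58 ± 0.32, SE, in 3 experiments), Marcksl1 (0.87 ± 0.24) and Vangl1, which was detected on 0 of the 3 control 24 h arrays and is given no value. Qser1 (-0.76 ± 0.23), Aebp2, a cofactor of the polycomb complex that methylates histones (-0.73 ± 0.20), and Sapcd2 (-0.66 ± 0.17) were on the lower side, and the adjusted p of all was 0.620. The giant cell genes were the 1 list called of 22 (median 0.61, adjusted p = 6.3e-05, 0 members passing over all genes and 0 adjusted over the list alone). That call was lost with an estimated correlation (adjusted p = 0.492 with an estimated correlation). Without the control 24 h arrays of experiments 19 and 27 it was lost too, and other lists were called, in a fit with 1 control array at 24 h. In limma 0 features were called, with 857 at an unadjusted p under 0.05, and 0 with 622 in a fit of the 1 h and 24 h arrays alone. Without the control 24 h array of experiment 15 the count was 988, without experiment 15 it was 614, and with array weights 1762.

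Control cultures changed between 1 h and 24 h. Psg18, a pregnancy-specific glycoprotein of the placenta, rose by 2.65 ± 0.36 on the log2 scale (SE, 4 arrays against 3), Gpnmb, a lysosomal membrane glycoprotein, by 2.29 ± 0.27 and Slc1a1, a glutamate and aspartate transporter, by 2.27 ± 0.35. Syp, the vesicle protein synaptophysin, rose by 2.27 ± 0.21 and Zdhhc14, a palmitoyltransferase, by 1.93 ± 0.16. Osbp2 (1.99 ± 0.47), Upk3b (1.94 ± 0.31), Hsd11b2, which inactivates glucocorticoids (1.89 ± 0.47), Chst8, a sulfotransferase (1.85 ± 0.35), and Cyp2d22, a cytochrome P450 (1.63 ± 0.36), also rose. Robo4, a receptor of endothelial cells, fell by 2.29 ± 0.42 and Prnd, a relative of the prion protein, by 2.38 ± 0.41, with adjusted p of 0.0039 and 0.0030. At 1 h, 1 of 4 arrays detected Slc1a1, 2 detected Syp, Osbp2, Upk3b and Cyp2d22, and 3 detected Psg18 and Chst8. At 24 h, 1 of 3 detected Robo4 and Prnd and 2 detected Upk3b. Across the 10 named rises the adjusted p ran from 3.7e-05 for Zdhhc14 to 0.016 for Hsd11b2.

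Another set of falls in the controls came mostly from experiments 19 and 27. Hmgb1, an abundant chromatin protein, fell by 3.63 ± 0.74, with values from -6.63 to -0.61 in the 3 experiments. Hspa5, the main chaperone of the endoplasmic reticulum, fell by 2.87 ± 0.58. The nucleosome-binding protein Hmgn2 (-3.0 ± 0.65), the translation initiation factor subunit Eif3m (-2.98 ± 0.68), the transcription factor Elf2 (-2.52 ± 0.62) and the alpha-tubulin Tuba1a (-2.52 ± 0.65) also fell. Of the 3 control 24 h arrays, 2 detected each of these but Hspa5, which all detected. Without the control 24 h arrays of those experiments Hmgb1 stood at -0.69, Hspa5 at -0.54, Hmgn2 at -0.15, Eif3m at -0.11, Elf2 at 0.04 and Tuba1a at -0.01, and none of the 6 was called. Outside that set, the granzymes Gzme and Gzmd, proteases of uterine natural killer cells, fell (-2.54 ± 0.77 and -2.31 ± 0.75). Without those arrays they stood at -2.56 (adjusted p = 0.255) and -2.40 (0.283), and leaving out 1 array or experiment ended their calls in 6 and 16 of 23 settings.

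Of the 20 named changes, 9 were called whichever array or experiment was left out (Psg18, Gpnmb, Slc1a1, Syp, Upk3b, Zdhhc14, Chst8, Prnd and Robo4), and 4 also without both of those control arrays. These were Slc1a1 (2.86, adjusted p = 0.0198), Syp (2.15, 0.0159), Gpnmb (2.01, 0.0411) and Zdhhc14 (1.98, 0.0084). Psg18 then had 1.87 (adjusted p = 0.0938) and Robo4 -1.97 (0.124). The other 11 lost the call in 2 to 16 of the 23 settings that leave out 1 array or experiment.

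**Figure D2:**
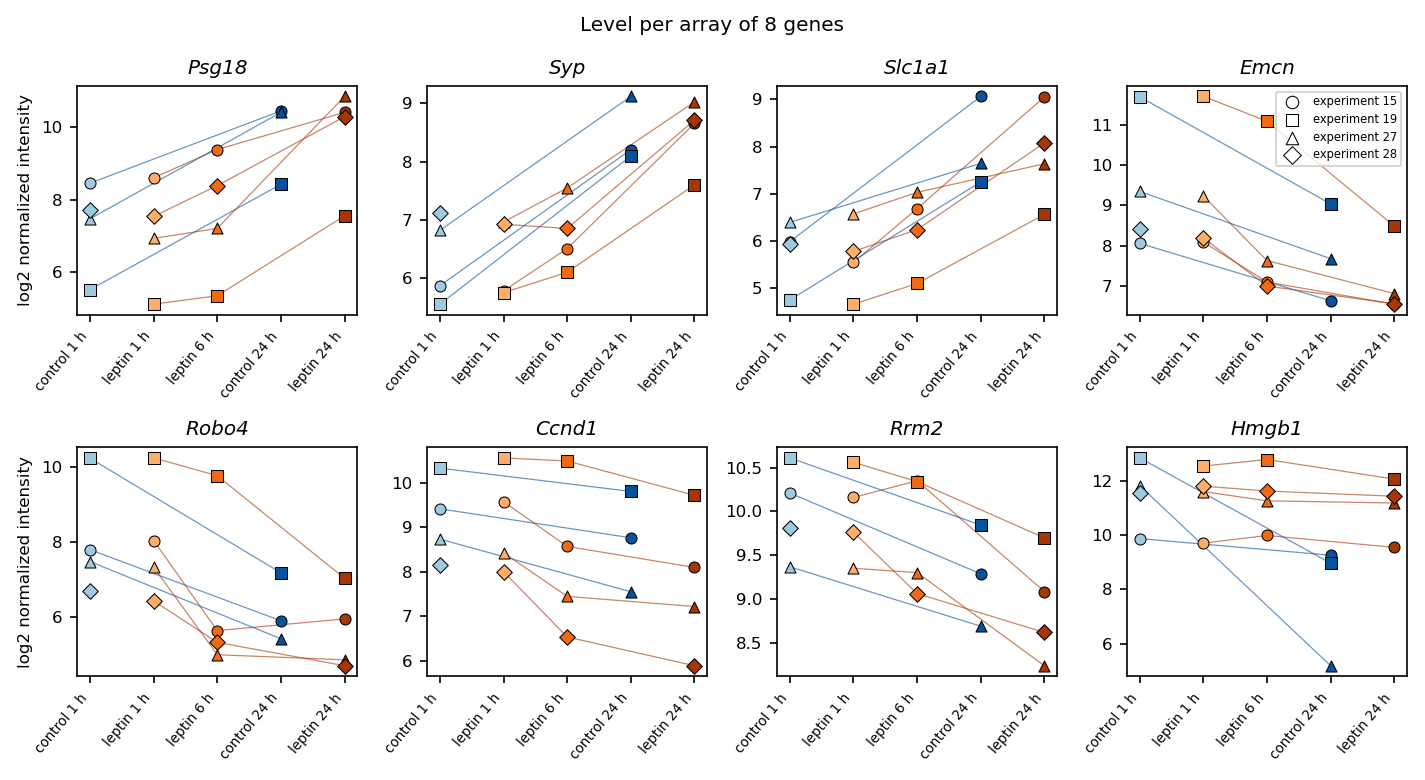
Level of 8 genes (log2 normalized intensity) on each array, by group, with shape for the experiment and lines joining the control arrays (blue) and the leptin arrays (orange) of 1 experiment. Psg18, Syp and Slc1a1 were higher and Robo4 and Rrm2 lower at 24 h than at 1 h in every experiment, with or without leptin, while the fall of Hmgb1 in the controls was 6.63 in experiment 27 and 0.61 in experiment 15.

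Cell cycle and proliferation genes fell together in the controls (15 tested, median -0.66, adjusted p = 5.0e-07, and 0.0256 with an estimated correlation). In a fit of the control arrays alone the call was lost with an estimated correlation (median -0.64, adjusted p = 3.5e-06, but adjusted p = 0.798 with an estimated correlation). Of the 15 members 10 were lower, and 11 adjusted over the list alone. Ube2c, a ubiquitin-conjugating enzyme of mitosis, was at least 1.02-fold lower, detected on 1 of 4 arrays at 1 h and 0 of 3 at 24 h. Ccnb1, the mitotic cyclin B1, fell by 1.22 ± 0.18, Foxm1, a transcription factor of proliferating cells, by 0.93 ± 0.19 and Rrm2, a subunit of ribonucleotide reductase, by 0.84 ± 0.16. The giant cell genes were lower (median -0.53, adjusted p = 0.0045), a call lost with an estimated correlation (adjusted p = 0.344 with an estimated correlation) and without the control 24 h arrays of experiments 19 and 27 (adjusted p = 0.683). Of their 10 members 4 were lower, and 6 adjusted over the list alone. These 4 were Prl3d2 (-2.13 ± 0.43), Prl3d3 (-2.05 ± 0.43), Prl7d1 (-2.01 ± 0.60) and Prl3d1 (-1.84 ± 0.34). Endothelial markers were lower (5 tested, median -0.79, adjusted p = 0.0214, but adjusted p = 0.493 with an estimated correlation). Over all genes and adjusted over the list alone 3 fell, namely Robo4, Emcn, the endothelial glycoprotein endomucin (-1.93 ± 0.34), and Eng, the TGF-beta co-receptor endoglin (-0.79 ± 0.19). The unfolded protein, amino acid and heat shock list was lower (9 tested, median -0.95, adjusted p = 0.0368, but adjusted p = 0.344 with an estimated correlation). Over all genes 5 members were lower, and adjusted over the list alone 5 were lower and 1 higher. Besides Hspa5 these included Hsp90aa1, a cytosolic chaperone (-1.51 ± 0.31), Phgdh, the first enzyme of serine synthesis (-1.37 ± 0.27), and Hspd1, a mitochondrial chaperone (-0.95 ± 0.22). Without the control 24 h arrays of experiments 19 and 27 the adjusted p was 0.357 for the endothelial list and 0.474 for the unfolded protein list. Without experiment 19 it was 0.122 and 0.247, and for the unfolded protein list 0.0711 without experiment 28.

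In limma 1874 features were called in the controls, 948 higher and 926 lower at 24 h. Of these 1621 had the same sign in every experiment, and 692 had a gene symbol (314 higher, 378 lower). The median SE of this comparison was 0.218, against 0.287 in a fit of the control arrays alone. The count was 0 in a limma fit of the control arrays alone (1521 at an unadjusted p under 0.05), 10 without the experiment block and 75 without the control 24 h arrays of experiments 19 and 27. Left-out arrays gave 709 (control 24 h of experiment 19), 775 (control 24 h of 27), 804 (control 1 h of 27), 885 (control 1 h of 19) and 3177 (control 24 h of 15), and left-out experiments 159 (27), 854 (19) and 1025 (28).

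**Figure D3:**
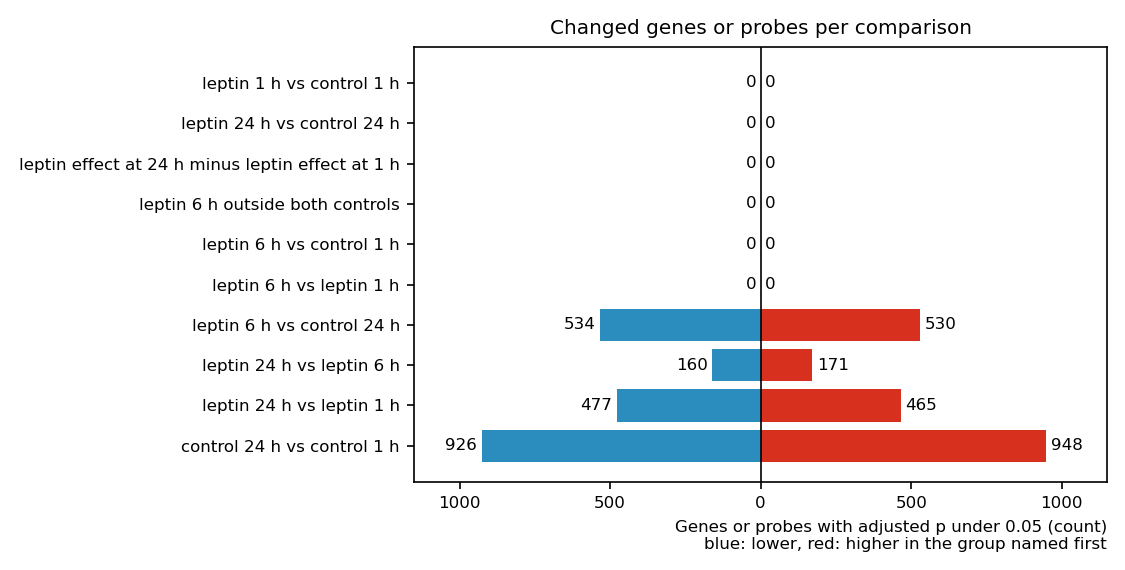
Number of genes or probes called in each comparison (limma, adjusted p under 0.05), with bars to the right for those higher and to the left for those lower in the group named first. The counts of leptin against control were 0 at 1 h and 0 at 24 h, and the counts of 24 h against 1 h were 948 higher and 926 lower in the controls and 465 higher and 477 lower with leptin.

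The change from 1 h to 24 h under leptin compared the 2 leptin arrays of each of the 4 experiments, while the control 24 h arrays entered only the error of the fit. Psg18 rose by 2.73 ± 0.33 on the log2 scale (SE, n = 4 pairs, adjusted p = 3.4e-04), Slc1a1 by 2.20 ± 0.32, Syp by 2.14 ± 0.19 (adjusted p = 4.2e-05) and Osbp2, an oxysterol-binding protein, by 1.83 ± 0.43. Robo4 fell by 2.37 ± 0.38, Emcn by 2.21 ± 0.31, Apoa2, an apolipoprotein of high-density lipoprotein, by 2.01 ± 0.28 and Prnd by 1.64 ± 0.37. The adjusted p of the 8 was at most 0.0154. All but Osbp2 and Prnd stayed called whichever array or experiment was left out. At 1 h, 1 of 4 arrays detected Slc1a1, 2 Osbp2 and 3 Psg18 and Syp, and at 24 h, 1 detected Robo4 and 2 Prnd. The call of Osbp2 ended without experiment 15 or 27, and that of Prnd without experiment 15 or 28, in each case 4 of 23 settings with single arrays counted.

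Of 15 cell cycle and proliferation genes 13 fell, over all genes and adjusted over the list alone (median -0.82, adjusted p = 3.3e-12, and 0.0028 with an estimated correlation). Ccnd1, the G1 cyclin D1, fell by 1.41 ± 0.24, Rrm2 by 1.05 ± 0.15, Ccnb1 by 0.85 ± 0.16 and Foxm1 by 0.84 ± 0.17. The list median lay between -0.94 and -0.77 in the 4 experiments. Endothelial markers were lower (median -0.79, adjusted p = 0.0040, but adjusted p = 0.447 with an estimated correlation). Of 5 markers 3 fell, over all genes and adjusted over the list alone, since Eng fell by 0.79 ± 0.18 beside Emcn and Robo4. Hypoxia and glycolysis genes were higher (15 tested, median 0.32, adjusted p = 0.0254, but adjusted p = 0.447 with an estimated correlation and 0.355 without experiment 27). Over all genes and adjusted over the list alone 1 member rose, the glycolytic enzyme Tpi1 (0.64 ± 0.14).

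In limma 942 features were called, 465 higher and 477 lower, and 898 had the same sign in all 4 experiments. The count was 144 in a fit of the 8 arrays of leptin 1 h and 24 h alone, 24 without the experiment block and 1469 without the control 24 h arrays of experiments 19 and 27. Left-out arrays that moved it by more than 1.5 times were those of leptin 1 h in experiments 15 (433), 27 (515) and 28 (526) and of leptin 24 h in experiment 15 (514), and left-out experiments were 15 (374), 27 (234) and 28 (366). Fitted on all 12 leptin arrays, those of 6 h included, and on the 7 control arrays, the changes from 1 h to 24 h correlated across features with r = 0.601 (Spearman 0.630), although features are not independent replicates. Of 902 features called in the fit of the 12 leptin arrays, 873 (96.8%) had the same sign in the controls.

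**Figure D4:**
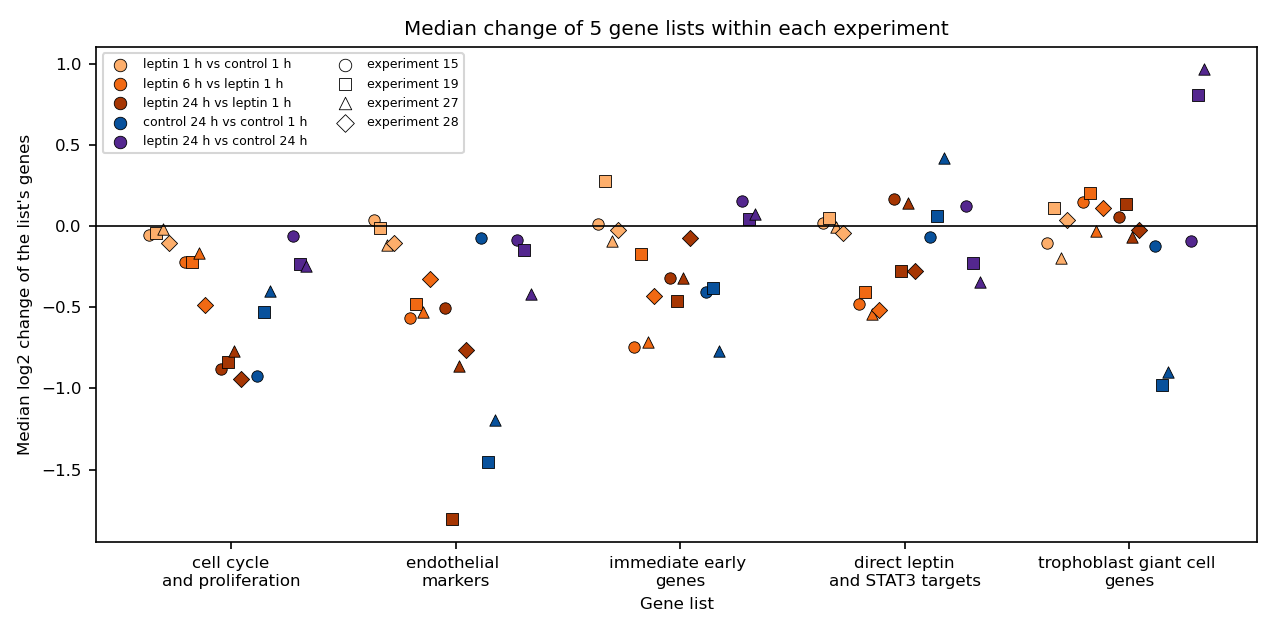
Median log2 change of 5 gene lists within each experiment (shape), for 5 comparisons (colour). The cell cycle list was below 0 in every experiment from 1 h to 24 h, between -0.94 and -0.77 with leptin and between -0.92 and -0.40 without it, and the giant cell list at 24 h was -0.09 in experiment 15 but 0.81 and 0.96 in experiments 19 and 27.

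From 6 h to 24 h of leptin, Psg18 rose by 2.19 ± 0.33 on the log2 scale (SE, n = 4 pairs), Gpnmb by 1.78 ± 0.24 and Syp by 1.74 ± 0.19 (adjusted p = 4.3e-04). Psg-ps1, of the same family as Psg18, was at least 1.45-fold higher, detected on 0 of 4 arrays at 6 h and 3 at 24 h. Chst1, a sulfotransferase, fell by 1.49 ± 0.34, Spc24, a kinetochore protein, by 1.42 ± 0.21, Slc16a6, of the monocarboxylate transporter family, by 1.37 ± 0.30 and Zfp184, a zinc finger protein, by 1.36 ± 0.29. The adjusted p of the 8 was at most 0.0310. Each call but that of Syp ended without experiment 27, those of Psg-ps1, Chst1, Spc24, Slc16a6 and Zfp184 also without experiment 28, and those of Chst1 and Slc16a6 without experiment 15. Counting single arrays too, the calls ended in 1 (Psg18) to 9 (Chst1) of 23 settings.

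The cell cycle list fell further over this interval (median -0.53, adjusted p = 8.3e-08, and 0.0173 with an estimated correlation). Of 15 members 5 were lower, and 7 adjusted over the list alone. Ccne2, a cyclin of the entry into DNA synthesis, fell by 1.10 ± 0.19, Rrm2 by 0.85 ± 0.15, Mcm7, a subunit of the replicative helicase, by 0.85 ± 0.15 and Tk1, thymidine kinase, by 0.64 ± 0.14. Of the markers of other cell types, Apoa2 (-1.19 ± 0.28, adjusted p = 0.0366) and Apoa1 (-0.76 ± 0.19, adjusted p = 0.0439) of the yolk sac list fell over the same interval. Esr1 of the decidual list, detected on 1 of 4 arrays at each time, rose by 0.95 ± 0.18 (adjusted p = 0.0147). Extracellular proteases, inhibitors and matrix genes were higher (11 tested, median 0.28, adjusted p = 0.0182, but adjusted p = 0.173 with an estimated correlation and 0.0994 without experiment 27). Over all genes 1 member rose, the metalloproteinase inhibitor Timp2 (0.78 ± 0.19), and 4 adjusted over the list alone. The spongiotrophoblast and glycogen cell list, markers of the junctional zone of the placenta, was called as higher (5 tested, median 1.14, adjusted p = 0.0436, but adjusted p = 0.358 with an estimated correlation). Its median was the value of Psg21, detected on 1 of 4 arrays at 6 h, and Ascl2 stood at -0.24 ± 0.25. Over all genes Psg18 was called, and 3 adjusted over the list alone. Without experiment 27 or 28 that list was not called (adjusted p = 0.263 and 0.0915).

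In limma 331 features were called between 6 h and 24 h of leptin, 171 higher and 160 lower, and 326 had the same sign in all 4 experiments. The count was 21 in a fit of these arrays alone, 3 without the experiment block, 715 without the control 24 h arrays of experiments 19 and 27, 6 without experiment 27, 41 without 28, 157 without 15 and 574 without 19. Left-out arrays moved it down to 58 (leptin 6 h of experiment 28), 99 (leptin 6 h of 27), 136 and 139 (leptin 24 h of 27 and 15), 200 (leptin 6 h of 15), 208 and 214 (control 1 h of 27 and 15) and 220 (leptin 6 h of 19), and up to 511 and 585 (control 24 h of 19 and 15).

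Between 1 h and 6 h of leptin no gene passed. Megf9 (0.86 ± 0.19, SE, n = 4 pairs), Mertk, a receptor tyrosine kinase for the uptake of dying cells (0.81 ± 0.17), and Rgs17, a regulator of G protein signalling (0.69 ± 0.16), had the smallest p on the higher side by the rule. Apol9a (-1.20 ± 0.23), Mx2, an interferon-induced GTPase (-1.06 ± 0.19), and Gask1b (-0.88 ± 0.17) had the smallest p on the lower side, with adjusted p of 0.111 each. Megf9 was detected on 1 of 4 arrays at 1 h and Apol9a on 1 of 4 at 6 h.

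Of the 22 lists, 8 were called at 6 h against 1 h of leptin, and a pair of these also with an estimated correlation. Immediate early genes were lower (9 tested, median -0.57, adjusted p = 6.4e-05, and 0.0126 with an estimated correlation). Over all genes 0 members were called, and 3 were lower adjusted over the list alone. Their values included -0.97 ± 0.19 for Fosl2 and -0.97 ± 0.31 for Junb, both components of the AP-1 transcription factor, -1.11 ± 0.46 for Klf2, a zinc finger transcription factor, and -0.78 ± 0.28 for Rhob, a small GTPase. Direct leptin and STAT3 targets were lower (10 tested, median -0.48, adjusted p = 7.1e-05, and 0.0126 with an estimated correlation), again with 0 called over all genes and 3 lower adjusted over the list alone. Socs2, a suppressor of cytokine signalling, stood at -0.68 ± 0.18, Ccnd1 at -0.88 ± 0.24 and Bcl2l1, an inhibitor of apoptosis, at -0.56 ± 0.24. Junb belongs to both lists, and Ccnd1 and Birc5 of the STAT3 list also belong to the cell cycle list.

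The other 6 lists called between 1 h and 6 h lost the call with an estimated correlation. Interferon response genes (median -0.10 but mean -0.45, adjusted p = 1.8e-04, 5 lower adjusted over the list alone) had an adjusted p = 0.280 with an estimated correlation. Their members Ifi47 and Ifit3 stood at -1.46 ± 0.40 and -1.37 ± 0.30. The cell cycle list (median -0.26, adjusted p = 1.8e-04, 1 lower adjusted over the list alone) had an adjusted p = 0.0569 with an estimated correlation. The endothelial list (median -0.49, adjusted p = 0.0071, 3 lower adjusted over the list alone) had an adjusted p = 0.361 with an estimated correlation. The protease and matrix list (median -0.22, adjusted p = 0.0126), the oxidative stress and NRF2 list (median 0.17, adjusted p = 0.0175) and the steroid hormone synthesis list (median 0.30, adjusted p = 0.0352) had 0 members called adjusted over the list alone. Their adjusted p = 0.119, 0.435 and 0.119 with an estimated correlation.

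In limma 0 features were called between 1 h and 6 h of leptin, with 803 at an unadjusted p under 0.05, and 0 with 1199 in a fit of these arrays alone. Without experiment 15 or 19 the count was 8, without the leptin 6 h array of experiment 19 it was 4, and with array weights 341.

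The design holds no control at 6 h, so leptin 6 h was set against the controls at 1 h and at 24 h, and both comparisons mix leptin with time in culture. Against control 1 h no gene passed. Mertk (0.78 ± 0.17, SE, n = 4 pairs), Usp20, a deubiquitinase (0.66 ± 0.14), and Trappc13, of a vesicle-tethering complex (0.57 ± 0.13), had the smallest p on the higher side by the rule. Nes, the intermediate filament nestin (-1.29 ± 0.25), and Mx2 (-1.02 ± 0.19) were those on the lower side, beside Cytip, which was detected on 0 of 4 arrays at 6 h and at least 1.25-fold lower. Nes was detected on 2 of 4 arrays at 6 h. The adjusted p was 0.145 for the lower genes and 0.182 to 0.212 for the higher ones.

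Against control 1 h, 9 of 22 lists were called, and 3 also with an estimated correlation. Cell cycle genes were lower (median -0.28, adjusted p = 1.5e-05, 6 lower adjusted over the list alone), and so were immediate early genes (median -0.52, adjusted p = 1.3e-04, 3 lower adjusted over the list alone). Direct leptin and STAT3 targets were also lower (median -0.55, adjusted p = 2.0e-04, 4 lower adjusted over the list alone), and each of the 3 lists had an adjusted p = 0.0196 with an estimated correlation. Ccnb1 stood at -0.61 ± 0.16, Fosl2 at -0.74 ± 0.19 and Socs2 at -0.64 ± 0.18. Over all genes 0 members of any list passed.

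The other 6 lists lost the call with an estimated correlation. Interferon response genes (median -0.11 but mean -0.42, adjusted p = 9.7e-04) and endothelial markers (median -0.66, adjusted p = 0.0029) each had an adjusted p = 0.331 with an estimated correlation. Adjusted over the list alone 5 and 3 of them were lower. Proteases and matrix (median -0.22, adjusted p = 0.0105) and steroid hormone synthesis (median 0.35, adjusted p = 0.0109) had an adjusted p = 0.0904 and 0.0671 with an estimated correlation. Oxidative stress and NRF2 targets (median 0.20, adjusted p = 0.0216) and inflammatory and NF-kB genes (median -0.44, adjusted p = 0.0475) had an adjusted p = 0.448 with an estimated correlation. In these last 4 lists 0 were called adjusted over the list alone. In limma 0 features were called, with 839 at an unadjusted p under 0.05, and 0 with 1191 in a fit of these arrays alone. Without experiment 15 the count was 11, without 19 it was 13, without the leptin 6 h array of experiment 19 or 27 it was 3 or 1, and with array weights 380.

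Against control 24 h, Hmgb1 was higher at 6 h of leptin by 3.52 ± 0.74 on the log2 scale (SE, 4 arrays against 3), Hmgn2 by 2.95 ± 0.65, Hspa5 by 2.85 ± 0.58 and Mdh2, the mitochondrial malate dehydrogenase, by 2.56 ± 0.65. Their adjusted p was 0.0149 to 0.0292. Psg18 (-2.37 ± 0.36), Gpnmb (-2.22 ± 0.27), Upk3b (-2.03 ± 0.31) and Syp (-1.86 ± 0.21, adjusted p = 9.8e-04) were lower. Upk3b was detected on 2 arrays of each group, and Hmgb1 and Hmgn2 on 2 of 3 control 24 h arrays. Without the control 24 h arrays of experiments 19 and 27 none of the 8 was called, and Hmgb1 stood at 0.58, Hmgn2 at 0.10, Hspa5 at 0.52 and Mdh2 at -0.10, while Syp stood at -1.73 with an adjusted p of 0.0855. Leaving out 1 array or experiment ended the calls in 1 (Syp, Gpnmb and Upk3b) to 8 (Mdh2) of 23 settings.

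Of the 22 lists, 4 were called against control 24 h, each with an adjusted p = 0.234 with an estimated correlation. Giant cell genes were higher (median 0.60, adjusted p = 0.0010, 4 of 10 members called and 6 adjusted over the list alone). Prl3d2 stood at 2.44 ± 0.43 and Prl3d1 at 2.08 ± 0.34. Cell cycle genes were higher (median 0.28, adjusted p = 0.0027, 6 of 15 called and 6 adjusted over the list alone), with Foxm1 at 0.77 ± 0.19. Unfolded protein and heat shock genes were higher (median 0.90, adjusted p = 0.010, 5 of 9 called, and 6 higher and 1 lower adjusted over the list alone), with Hsp90aa1 at 1.57 ± 0.31. Direct leptin and STAT3 targets were lower (median -0.47, adjusted p = 0.0419, 1 of 10 called, Bcl2l1 at -0.87 ± 0.26, and 3 adjusted over the list alone). Without the control 24 h arrays of experiments 19 and 27 the adjusted p was 0.492 for giant cell genes, 0.429 for unfolded protein genes and 0.465 for STAT3 targets. Without experiment 15 it was 0.173 for cell cycle genes and 0.115 for STAT3 targets, without 27 it was 0.113 for STAT3 targets, and without 19 it was 0.118 for unfolded protein genes.

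In limma 1064 features were called against control 24 h, 530 higher and 534 lower at 6 h of leptin, with 915 of one sign in every experiment. The median SE was 0.218, against 0.259 in a fit of these arrays alone. The count was 0 in a fit of these arrays alone (1355 at an unadjusted p under 0.05), 0 without the experiment block and 0 without the control 24 h arrays of experiments 19 and 27. Single arrays left out gave 85 and 149 (control 24 h of 27 and 19), 2824 (control 24 h of 15), 204, 249 and 438 (leptin 6 h of 27, 19 and 28), 658 and 708 (control 1 h of 28 and 27) and 697 (leptin 1 h of 28). Experiments left out gave 3 (27), 89 (28), 106 (19) and 2193 (15).

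No gene was called on the same side of both controls at 6 h of leptin. By the rule, Terf2ip, a telomere protein, stood at 0.49 ± 0.13 against control 1 h and 0.43 ± 0.15 against control 24 h (SE, n = 4 and 3 pairs), Pradc1 at 0.48 and 0.78 and Prpf4, a splicing factor, at 0.37 and 0.39. Als2cl and Zfp24 stood at 0.63 and 0.49 against control 1 h and were detected on 0 of 3 control 24 h arrays, with at least 1.17-fold and 1.06-fold higher levels at 6 h of leptin. Gask1b stood at -0.80 and -0.74, Fosl2 at -0.74 and -0.83 and Dusp11, an RNA phosphatase, at -0.62 and -0.92. Cldn4, a tight junction protein, stood at -0.61 and -0.59 and Mafg, a small Maf transcription factor, at -0.56 and -0.77. Their adjusted p against control 1 h was 0.182 to 0.564. In limma 0 features passed against both, with 187 at an unadjusted p under 0.05 in both with one sign. The count was 8 without experiment 15, 1 without experiment 19 and 159 with array weights.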

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

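The tests of explanations in this part were chosen only after the results were seen. Array values and changes per experiment were compared within groups of 4 by the gap of the highest or lowest value to the nearest other, divided by the range. Chance puts about 1 in 20 groups past that limit, and 6 of 24 groups of array values, 1 of 48 of gene changes and 1 of 23 of list medians were past it.

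All 6 array values past the limit belong to smaller-version arrays of experiment 19. The control 1 h array of experiment 19 had 10724 detected probes against 9124 to 9383 in the other experiments. Its first principal component was 75.98 against -17.26 to -7.94. The leptin 1 h array of experiment 19 had a first component of 76.04 against -18.88 to -9.35. The leptin 6 h array of experiment 19 had a mean signal of 1012 against 792 to 827. Its first component was 71.86 against -26.74 to -11.71. The leptin 24 h array of experiment 19 had a first component of 57.38 against -29.20 to -20.27. In leptin against control at 1 h, the change of Slc4a3 was 1.53 in experiment 27 against 0.09 to 0.21 in the others. From 1 h to 6 h of leptin, the median of the oxidative stress and NRF2 list was 0.25 in experiment 19 against 0.11 to 0.12 in the others. The giant cell genes differed between the leptin effects at 24 h and at 1 h (adjusted p = 6.3e-05 for the difference, and 0.492 with an estimated correlation).

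The first pattern is the size of the differences between leptin and control at 24 h in experiments 19 and 27, where 1539 and 980 features differed more than 2-fold, against 51 in experiment 15, and 626 did so the same way in both (606 lower in control, 20 higher). The array version as the whole cause is argued against by the 980 features of experiment 27, whose arrays are all of the larger version, although in experiment 19 it cannot be separated from the treatment. A shift between preparations that also occurs without a treatment difference is a candidate explanation, whose nature was not tested: across features, which are not independent, control minus leptin in experiment 27 correlated with experiment 15 minus experiments 27 and 28 in the other groups (r = 0.457, and 0.437 for experiment 19 but -0.09 for experiment 15). With experiment 19 minus experiments 27 and 28, where the array version differs too, r was -0.243 for experiment 27, -0.442 for experiment 19 and 0.204 for experiment 15, so only the first of these 2 axes gave a positive r in experiments 19 and 27. Leptin as the cause cannot be told apart from the state of the 3 control cultures or their arrays, 1 per culture. Those 626 features moved by a median of -0.29 (SD 0.34) in experiment 15 in the direction that gave 1.98 and 1.69 in experiments 19 and 27. They included the ribosomal protein genes Rpl36al (leptin minus control 5.27 and 3.92 in experiments 19 and 27), Rps6 (3.08 and 5.70) and Rpl30 (3.91 and 3.03). In experiment 15 these stood at -0.87, -0.49 and -0.99. Whether RNA or array quality differed was not tested.

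The second pattern is the fall of cell cycle genes between 1 h and 24 h. Leptin as the whole cause is argued against by the controls, where the list median had a mean of -0.62 (SD 0.27) over 3 experiments, although in the control arrays alone the call was lost with an estimated correlation (median -0.64, adjusted p = 3.5e-06, but 0.798 with an estimated correlation). The scaling of the arrays is argued against by the adjusted p of at most 6.8e-12 under median scaling (list median -0.86) and cyclic loess (-0.82). Loss of all other cell types alike is argued against by the markers of other cell types, since under leptin the leukocyte list median exceeded the endothelial one by 1.10 (SD 0.53, 4 experiments). A decline of proliferation in culture stays open as a hypothesis, and so does a loss of endothelial cells, of yolk sac cells (under leptin Apoa2 -2.01 and Apoa1 -1.42 were called but Trf -0.44 and Apoc2 -0.13 were not) or of erythroid cells (Hba-x -1.36, called).

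The third pattern is the lower level of immediate early genes at 6 h than at 1 h of leptin. Induction by leptin at 1 h that ended by 6 h would need a rise of 0.57 at 1 h. For the 9 tested genes of the 38 in the list it is argued against by the list median at 1 h. The mean of that median over 4 experiments was 0.045 (SD 0.16, highest 0.28). That value does not cover the untested members, and it rests on the 1 h labels of the controls. A decline with time in culture without leptin cannot be told apart from an effect of leptin at 6 h, since the design has no control at 6 h. The list median was -0.54 from 1 h to 24 h in the controls (adjusted p = 0.117) and 0.028 from 6 h to 24 h of leptin.

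The fourth pattern is the lower level of direct leptin and STAT3 targets at 6 h than at 1 h of leptin. Induction by leptin at 1 h that ended by 6 h would need a rise of 0.48 at 1 h. For the 10 tested genes of the 27 in the list it is argued against by the list median at 1 h. The mean of that median over 4 experiments was 0.0059 (SD 0.04). That value does not cover the untested members or Socs3, and it rests on the 1 h labels of the controls. A decline with time in culture without leptin that lasts to 24 h would need a median near -0.48 in the controls. It is argued against by their mean of 0.14 (SD 0.25) over 3 experiments, but only as far as these control arrays can be trusted. The medians were -0.07 in experiment 15, 0.06 in experiment 19 and 0.42 in experiment 27. The control 24 h arrays of experiments 19 and 27 stand apart, and without them the argument rests on the single control 24 h array of experiment 15. An effect of leptin at 6 h cannot be told apart from a decline in culture that passes before 24 h, since the design has no control at 6 h. From 6 h to 24 h of leptin the list median was 0.33 (adjusted p = 0.0812), and it lay between 0.22 and 0.50 in the 4 experiments.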

How the results depend on the processing

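The alternatives with the array version as a block, with the larger version alone and without the control 24 h arrays of experiments 19 and 27, and every test of leptin 24 h against leptin 1 h, were chosen only after the result was seen. The count of called features stayed within 1.5 times its value in all comparisons under median scaling, cyclic loess, detection on all 19 arrays, every tested probe, a further minimum of 1.5-fold and the experiment as a random block (correlation 0.536). Median scaling shifted the balance to 613 higher and 1078 lower in control 24 h against control 1 h, 556 and 318 in leptin 6 h against control 24 h, 101 and 218 in leptin 24 h against leptin 6 h, and 364 and 558 in leptin 24 h against leptin 1 h. Detection on all 19 arrays gave 796 higher and 580 lower, 375 and 519, 214 and 202, and 438 and 386 in the same 4 comparisons.

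The paired design carries the counts. With no replicate block, control 24 h against control 1 h gave 10, leptin 6 h against control 24 h 0, leptin 24 h against leptin 6 h 3 and against leptin 1 h 24. With the replicate block but only the groups compared, the same counts were 0, 0, 21 and 144, where fewer arrays estimate the error. For the comparisons with control 24 h the error was also larger there (median SE 0.287 and 0.259, against 0.218 with all arrays). For the others it was 0.185 and 0.192, against 0.198. The fit of all arrays thus gave the comparisons with control 24 h a smaller error than their own arrays gave. At an adjusted p under 0.10 they were 2938, 2172, 722 and 1476. Without background correction, and in the deposited log2 table, leptin against control at 24 h gave 1. No filter on dim probes gave 634 in leptin 6 h against control 24 h, with more features tested. Trended and robust moderation gave 2 in leptin 6 h against control 1 h.

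Array weights, in a fit that did not converge and gave the control 24 h array of experiment 27 a weight of 11.1, called 2531 in leptin against control at 24 h, 1762 in its difference from 1 h, 6250 in control 24 h against control 1 h, 380 in leptin 6 h against control 1 h, 4881 against control 24 h, 341 against leptin 1 h, 1650 in leptin 24 h against leptin 1 h and 159 outside both controls. With the array version as a further block, control 24 h against control 1 h gave 709, leptin 6 h against control 24 h 149 and leptin 24 h against leptin 6 h 511. These are the counts without the control 24 h array of experiment 19, the only array whose version differs within its experiment. The block removes that array and is no separate test of the version. The larger version alone gave 854 for control 24 h against control 1 h, 13, 106 and 8 for leptin 6 h against control 1 h, control 24 h and leptin 1 h, 574 for leptin 24 h against leptin 6 h and 1 outside both controls. These are the counts without experiment 19, so that setting cannot part the version from the experiment. Without the control 24 h arrays of experiments 19 and 27, which leaves 1 control array at 24 h that is assumed to vary like the other groups, control 24 h against control 1 h gave 75 (60 of them among the 1874), leptin 6 h against control 24 h 0, leptin 24 h against leptin 6 h 715 and against leptin 1 h 1469, while Elf2 in the controls reversed to 0.043 and Mdh2 in leptin 6 h against control 24 h to -0.10.

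Leaving out 1 array or experiment gave 0 in leptin against control at 1 h, 0 to 1812 at 24 h and 0 to 988 for their difference. It gave 159 (without experiment 27) to 3177 (without the control 24 h array of experiment 15) in control 24 h against control 1 h, 0 to 13 in leptin 6 h against control 1 h, 3 (without experiment 27) to 2824 (without the control 24 h array of 15) against control 24 h and 0 to 8 against leptin 1 h. Leptin 24 h gave 6 (without experiment 27) to 585 (without the control 24 h array of 15) against leptin 6 h and 234 (without experiment 27) to 1379 (without experiment 19) against leptin 1 h, and 0 to 8 were outside both controls. The cause was not tested. Of 3716 values of named genes under an alternative, 3288 kept direction and side of the threshold, 352 lost the call, 74 gained it and 2 reversed. Genes never called count as kept there, so that share does not measure how firm the calls are. Among called named genes, 9 of 20 in control 24 h against control 1 h stayed called whichever array or experiment was left out. The same held for 0 of 8 in leptin 6 h against control 24 h. For leptin 24 h it held for 1 of 8 against leptin 6 h and 6 of 8 against leptin 1 h. Of 363 values of called lists, 282 stayed called, 81 lost the call and 0 reversed. With fry, 0 lists were called in leptin against control at 1 h, 0 at 24 h and 0 for their difference. Fry called 7 in control 24 h against control 1 h, and for leptin 6 h 4 against control 1 h, 5 against control 24 h and 4 against leptin 1 h. For leptin 24 h it called 3 against leptin 6 h and 5 against leptin 1 h. Signal over background limits the genes near the detection limit.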

Other observations

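Tests on the other splits of comparisons with a count of 0, and the drawn splits that part every pair, were chosen only after the result was seen. Between 1 h and 24 h of leptin, single members of several lists changed. Dcn, the matrix proteoglycan decorin, rose by 1.23 ± 0.21 on the log2 scale (SE, n = 4 pairs, adjusted p = 0.0027), Esr1, the estrogen receptor alpha, by 0.89 ± 0.18 (adjusted p = 0.0082), Ptges, a prostaglandin E synthase, by 0.87 ± 0.23, Timp2 by 0.84 ± 0.19, Abcg1, a cholesterol exporter, by 0.80 ± 0.18 and Cdh3, placental cadherin, by 0.46 ± 0.13. Acta2, smooth muscle actin, fell by 1.57 ± 0.33, Apoa1, the main apolipoprotein of high-density lipoprotein, by 1.42 ± 0.19, Phgdh by 1.34 ± 0.24, Hba-x, an embryonic globin, by 1.36 ± 0.41 (adjusted p = 0.0495), Id3, an inhibitor of differentiation factors, by 1.08 ± 0.24, Ifit3 by 1.12 ± 0.30 and Mx2 by 0.73 ± 0.19, both interferon-induced, Tgfb2, a TGF-beta ligand, by 0.77 ± 0.19 and Msn, the membrane linker moesin, by 0.72 ± 0.18. The call of Hsd11b2 (1.63 ± 0.43, adjusted p = 0.0280) held the same sign in 3 of 4 experiments. At most 1 array of each group detected Esr1, and 2 of 4 detected Ptges at 1 h and 1 of 4 Ifit3 at 24 h. Leaving out arrays was not run for the genes of this paragraph.

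In the controls over the same interval, Abcg1 (1.29 ± 0.20), Timp2 (1.04 ± 0.21), Fabp3, a fatty acid binding protein (0.75 ± 0.21), Irf1, an interferon regulatory factor (0.67 ± 0.21), and Star, the mitochondrial cholesterol carrier (0.64 ± 0.18), rose, and Ptges, detected on 0 of 4 arrays at 1 h, was at least 1.71-fold higher. Apoa2 (-1.83 ± 0.31), Apoa1 (-1.44 ± 0.21), Ptgs2, the inducible cyclooxygenase (-1.61 ± 0.44), Ifi47 (-1.89 ± 0.44), Ccn1, a matricellular immediate early gene (-1.32 ± 0.34), Id3 (-1.21 ± 0.27), Itga6, a laminin receptor subunit (-1.15 ± 0.26), and Mx2 (-0.98 ± 0.21) fell, each within a fit whose count was 75 rather than 1874 without the control 24 h arrays of experiments 19 and 27. The 4 globin genes tested stood between -1.51 and -1.08 in the controls and between -1.68 and -0.96 with leptin, and of these Hba-x passed in both (adjusted p = 0.0495 each). At most 1 array of each group detected Star, and at 24 h 1 of 3 detected Ifi47 and 2 Ptgs2. Leprot, a gene that shares its promoter with the leptin receptor gene, rose in the controls by 0.57 ± 0.18, with the same sign in 2 of 3 experiments.

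The counts of called features were set against other splits of the same arrays into groups of the same sizes. Since the experiment pairs the arrays, the fair comparison is with the 8 of 35 splits that part every pair, and these are too few for a share under 0.05. Each of the other 27 puts both arrays of at least 1 experiment in one group. In leptin 24 h against leptin 1 h the real split gave 942 and the highest other 0, among the 8 and among all 35 (1 of 35 as large). In leptin 24 h against leptin 6 h the real split gave 331 and the highest other 1, among the 8 and among all 35 (1 of 35 as large). In control 24 h against control 1 h the real split gave 1874, the highest other of the 8 gave 368 and that of the 35 gave 943 (1 of 35 as large). In leptin 6 h against control 24 h the real split gave 1064, the highest other of the 8 gave 2 and that of the 35 gave 675 (1 of 35 as large). In these last 2 comparisons the highest of the 35 keep the control 24 h arrays of experiments 19 and 27 together and point to a structure of the samples, and fits of only the groups compared gave 0 and 0.

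Where the real count was 0, every split is as large whatever the data, so the splits test nothing there, and their counts are given only for the highest other. This holds for leptin against control at 1 h (35 of 35, highest other 4, and 0 among the 8), leptin 6 h against control 1 h (35 of 35, highest other 0) and leptin 6 h against leptin 1 h (35 of 35, highest other 0). It holds too for 2 results with 100 drawn splits that part every pair and 100 that need not: leptin 6 h outside both controls (100 of 100 in each set, highest other 0) and the difference of the leptin effects (100 of 100 in each set, highest other 0 with every pair parted and 399 without). For leptin against control at 24 h (35 of 35), the highest other split called 1481 and set control 24 h of experiment 15 with leptin 24 h of experiments 15, 27 and 28. Among the 8 that part every pair the highest was 638, with the arrays of experiment 15 exchanged, which again points to a structure of the samples, since both keep the control 24 h arrays of experiments 19 and 27 together.

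For the number of called lists, the 8 splits that part every pair are again too few for a share under 0.05. The real number and the highest other of the 8 were 1 and 4 in leptin against control at 24 h (33 of all 35 splits as large), 4 and 4 in control 24 h against control 1 h (6 of 35) and 9 and 3 in leptin 6 h against control 1 h (4 of 35, highest other 10). They were 4 and 5 in leptin 6 h against control 24 h (9 of 35), 8 and 3 against leptin 1 h (3 of 35, highest other 8), 3 and 6 in leptin 24 h against leptin 6 h (25 of 35) and 3 and 6 against leptin 1 h (20 of 35). For the difference of the leptin effects chance cannot be excluded (74 of 100 drawn splits that part every pair as large, real 1, highest other 6, and 88 of 100 without that condition).

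For single lists the real split had the lowest adjusted p of the 8, which are too few here as well. The adjusted p and the lowest of the other 7 were 3.3e-12 and 3.4e-08 for cell cycle genes in leptin 24 h against leptin 1 h (1 of all 35 splits as low), 8.3e-08 and 6.4e-07 against leptin 6 h (2 of 35) and 5.0e-07 and 5.8e-07 in control 24 h against control 1 h (3 of 35). For leptin 6 h against leptin 1 h they were 7.1e-05 and 0.018 for STAT3 targets (1 of 35) and 6.4e-05 and 3.4e-04 for immediate early genes (3 of 35). For the giant cell genes at 24 h they were 2.3e-05 and 1.5e-04 (1 of 35), with 0.399 for the real split with an estimated correlation.

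The 1418 probes that only the larger array version carries were outside the comparisons. Of the 602 tested on the 15 arrays of that version with limma, leptin against control gave 0 calls at 1 h (0 at an unadjusted p under 0.05) and 0 at 24 h (32 at an unadjusted p under 0.05). Control 24 h against control 1 h gave 50, leptin 24 h against leptin 1 h 63, leptin 6 h against control 24 h 19 and leptin 24 h against leptin 6 h 17.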
